A study of Mus musculus with 16 samples.

How the data were processed

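The deposited files hold 1 table per library of reads counted per gene, and the count values were used as the authors deposited them, with no normalization applied before deposit. Per the submitters' processing notes, Trimmomatic and STAR were used with the mouse build mm10. Their versions, settings and gene annotation are not given in the sources used here. The labels give RNA-STAT60 extraction, selection of polyadenylated RNA with poly-T beads and Illumina sequencing. Each table has 24411 gene symbols, 4 categories that are not genes, and 3 count columns. The unstranded column was used, since the 2 stranded columns split the reads nearly evenly (50.58% to 51.79% in 1 of them). Reads without a gene feature made up 9.397% to 10.87% of a library and ambiguous reads 1.348% to 1.693%. Unmapped reads made up 11.57% to 19.89%.

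Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 12901 genes, and libraries were scaled by TMM with factors of 0.863 to 1.269. A model with 1 mean per group was fitted to all 16 libraries with edgeR 4.0.16 (quasi-likelihood), and 4 pairwise contrasts and their interaction were tested. P-values were adjusted by Benjamini-Hochberg over all tested genes of a contrast, with 0.05 as the limit. Levels are CPM from TMM-scaled library sizes, and log2 CPM used a prior count of 2. The other tools were R 4.3.3, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

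The 35 gene lists, with 655 members of which 557 were tested, the contrasts, the alternatives and the naming rule were fixed before the data were examined. Lists with at least 5 tested members were tested with limma's camera on log2 CPM, with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Adjusted p-values of lists are over the lists of a contrast. Counts adjusted over the list alone use the edgeR p-values of the members only. A list score is the mean log2 CPM of its measured members, relative to the mean of the PF libraries. The groups of ribosome assembly, keratin and cytoskeleton, and hepatocyte transcription factor genes were drawn up after the values were seen.

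Genes are named by a rule. For each contrast it takes the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and no overlap of replicates. For the interaction it asks for the adjusted p and at least 1 CPM in the highest group. To these it adds up to 4 members per list with the smallest p, and 21 fixed genes, of which 18 were tested. Predicted gene models and pseudogenes are counted but not named, and some genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen.

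Gene coordinates come from an annotation of GRCm38, which matched 23194 of the 24411 symbols. The libraries are not strand-specific, so reads of genes that overlap on opposite strands cannot be parted. STAR counts only reads that map to 1 place, so genes with near-identical copies lose reads.

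The fit was tested on simulated data with the library sizes and gene-wise spread of these libraries. It recovered 72% of 2-fold and 95% of 4-fold changes in EtOH against PF, 70% and 93% in EtOH+MBV against EtOH, 67% and 93% in PF+MBV against PF, 66% and 92% in EtOH+MBV against PF+MBV, and 47% and 77% in the interaction. The false share of calls was 5.65%, 1.81%, 4.76%, 5.95% and 3.88%. Each contrast was simulated a single time, with 100 genes changed 2-fold and 100 changed 4-fold and no diet effect. Genes were drawn on their own, with the same spread in all groups and no library set apart. The shares may therefore be better than these libraries allow. Shared controls were handled by simulating counts with no MBV effect, with each gene drawn on its own. In addition, 2 EtOH libraries were used for one contrast and the other 2 for the other. Single values such as read shares were compared by 2-sided exact permutation tests of 4 against 4 libraries.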

Results

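Polyadenylated RNA was sequenced from the livers of mice in 4 groups of 4 libraries. PF mice were pair-fed a control diet and given vehicle, and EtOH mice were given vehicle on an ethanol diet that followed the NIAAA model of chronic and binge drinking. EtOH+MBV and PF+MBV mice had the same diets with matrix-bound nanovesicles (MBV), small vesicles held within the extracellular matrix. The design asks how ethanol changes the liver, how MBV changes it on each diet, and whether MBV acts differently on the 2 diets. The 16 libraries held 15.3 to 20.5 M counts in genes, with 15021 to 15856 genes detected in each, and 12901 genes were tested. Adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Errors of fold changes are standard errors from the same fit of all 16 libraries (n = 4 per group), which shares a single spread per gene over the groups. The groups spread unequally. The chi-square per degree of freedom between the counts of paired libraries was 8.72 to 16.4 within PF+MBV and 27.4 to 166 within EtOH. Errors and p-values may therefore be too small in EtOH+MBV against EtOH and too large in PF+MBV against PF. Levels are given in CPM, counts scaled to library size, as mean ± SD. The labels do not say that the replicates are separate mice, so p-values measure only the spread between these samples.

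The diets separated on the first principal component of log2 CPM, which held 49.8% of the variance. On this component EtOH+MBV 1 lay at -0.3, and the other 3 EtOH+MBV libraries lay at 41.2 to 49.6. The second component, with 15.6% of the variance, set EtOH 1 apart at -74.2. Reads that did not map made up 18.32% ± 1.88 (SD, n = 4) of the PF libraries, 12.68% ± 0.897 of EtOH, 12.57% ± 0.901 of EtOH+MBV and 14.93% ± 0.742 of PF+MBV. The EtOH and PF shares differed with p = 0.0286 in a 2-sided exact permutation test, the smallest p that 4 against 4 can give, and adjusted p = 0.0857 over 12 such tests.

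**Figure D1:**
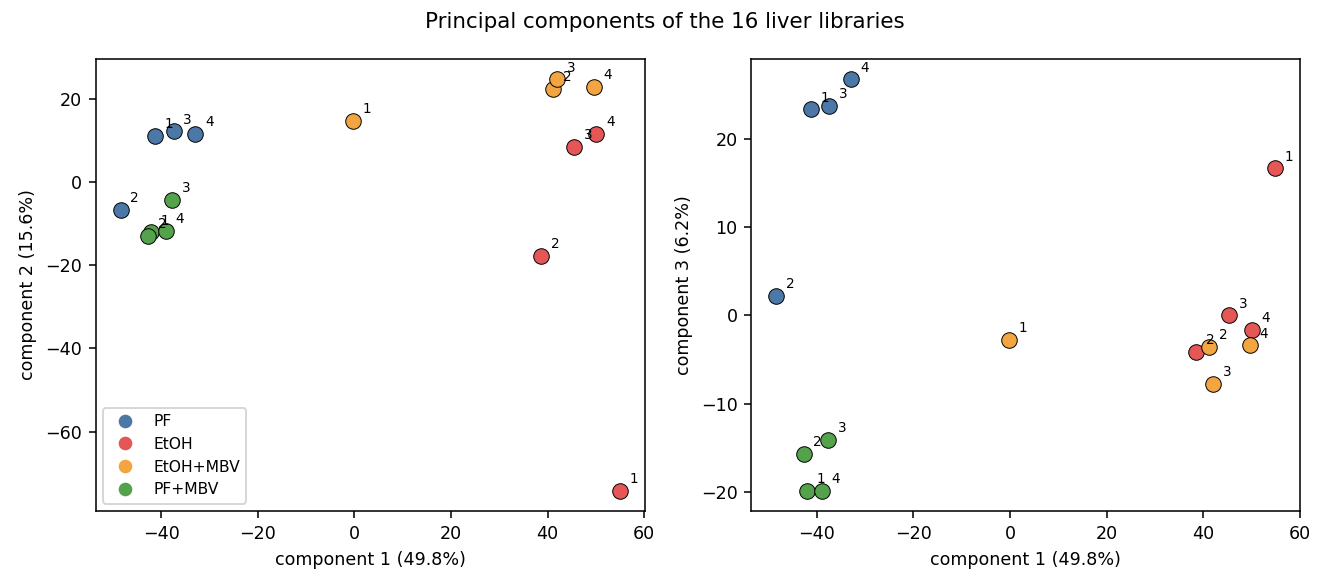
Scores of the 16 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, with each point a library, colours for the 4 groups and digits for the replicates. EtOH+MBV 1 lies at -0.3 on component 1 and EtOH 1 at -74.2 on component 2.

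With ethanol, 17 of 23 NRF2 and metal response genes rose and all 13 male-biased liver genes fell, and Cyp7a1 of bile acid synthesis and the desaturase Scd1 were lower. Cyp2b10, a cytochrome P450 induced through the nuclear receptor CAR, rose 130-fold from 10.92 ± 10.4 to 1416 ± 314 CPM (log2 7.02 ± 0.81, edgeR adjusted p = 1.1e-05). Gstm3, a glutathione transferase, rose 67.4-fold from 19.28 ± 1.6 to 1301 ± 190 CPM (log2 6.08 ± 0.41, adjusted p = 1.94e-07). Hsd3b5, a steroid dehydrogenase of the male liver, was at 110.9 ± 91 CPM in PF and 0.127 ± 0.119 CPM in EtOH (log2 -9.79 ± 1.22, adjusted p = 2.03e-05). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 26.1-fold lower, at 13.1 ± 8.54 against 343.3 ± 159 CPM (log2 -4.71 ± 0.86, adjusted p = 0.000551). Of 12901 genes, 5137 passed an adjusted p of 0.05, 2627 higher and 2510 lower with ethanol, and 1794 of them changed at least 2-fold. In the mm10 build (GRCm38), Cyp2b10 lies on chromosome 7 from 25897658 to 25926624, Gstm3 on chromosome 3 from 107963696 to 107969174, Hsd3b5 on chromosome 3 from 98618636 to 98645534 and Cyp7a1 on chromosome 4 from 6265612 to 6275632.

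Of the 23 measured genes of the NRF2 and metal response, 17 rose and 1 fell in EtOH, with the same counts when adjusted over the list alone. They included Gsta1 (133-fold), Cbr3 (48.6-fold), Srxn1 (14.6-fold) and Nqo1 (11-fold), which detoxify electrophiles or restore oxidised proteins. Among 17 targets of CAR, PXR and AHR, 12 rose and none fell, and 14 rose when adjusted over the list alone. For both lists camera gave adjusted p = 1.2e-08 and 4.9e-07 with a preset correlation, and adjusted p = 0.23 with an estimated correlation. All 13 male-biased liver genes fell over all genes and when adjusted over the list alone, among them Cyp4a12b (29.7-fold) and the transporter Slco1a1 (11.3-fold). Mup21, a major urinary protein outside that list, fell 85.2-fold. Of 14 female-biased genes only 6 passed the count filter, and of these 5 rose, or 6 when adjusted over the list alone. Among them were Cyp2b9 (389-fold) and Cyp2a4 (333-fold), which were at 0.148 ± 0.132 and 0.139 ± 0.163 CPM in PF. Genes this low in pair-fed livers can pass the filter only through the ethanol groups, so the filter in part sets the share that rose. The male-biased and female-biased lists had camera adjusted p = 1.2e-08 and 0.0076, and adjusted p = 0.34 and adjusted p = 0.38 with an estimated correlation. Cyp2b, Cyp2a, Cyp4a, Gst and Mup genes belong to families of near-identical copies that share reads, so their single values are uncertain.

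Stress and early response genes rose as well. Of 17 immediate early genes 15 rose, Egr1 by 40.5-fold, with 15 when adjusted over the list alone (camera adjusted p = 1.2e-08, and adjusted p = 0.23 with an estimated correlation). Of 22 ER stress genes 15 rose, and 17 when adjusted over the list alone, with Atf3 at 63.6-fold, Trib3 at 25.1-fold and Ddit3, the CHOP factor, at 11.9-fold (camera adjusted p = 2.8e-05, and adjusted p = 0.6 with an estimated correlation). Psat1, an enzyme of serine synthesis, rose 50.1-fold. The p53 target Cdkn1a, a brake on the cell cycle, rose 23-fold, and 10 of 20 genes of its list rose and 1 fell, or 11 and 1 when adjusted over the list alone (camera adjusted p = 0.002, and adjusted p = 0.34 with an estimated correlation). Of 26 acute phase genes 13 rose and 2 fell, or 15 and 2 when adjusted over the list alone, with the iron-binding Lcn2 38-fold higher (camera adjusted p = 0.0049, and adjusted p = 0.67 with an estimated correlation). Of 19 inflammatory cytokines and chemokines 11 rose and 1 fell by either adjustment, among them Cd14, the lipopolysaccharide co-receptor, at 11.3-fold and the neutrophil attractant Cxcl1 at 5.35-fold (camera adjusted p = 0.0074, and adjusted p = 0.38 with an estimated correlation). Of 33 extracellular matrix genes 16 rose and 2 fell, or 18 and 2 when adjusted over the list alone (camera adjusted p = 0.00051, and adjusted p = 0.66 with an estimated correlation).

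Lists of lipid and sugar metabolism were mixed with ethanol. Of 20 genes of de novo lipogenesis 12 fell and 2 rose by either adjustment, with the desaturases Scd1 6.13-fold and Fads2 3.96-fold lower (camera adjusted p = 0.00042, and adjusted p = 0.41 with an estimated correlation). Of 23 genes of fatty acid oxidation 12 fell and 3 rose, or 13 and 3 when adjusted over the list alone. The receptor Ppara was 3.7-fold lower, while Pdk4, which spares glucose, was 11.5-fold higher (camera adjusted p = 0.0033, and adjusted p = 0.67 with an estimated correlation). Of 18 glucose metabolism genes 2 rose and 6 fell, or 2 and 7 when adjusted over the list alone, with the glucose-6-phosphatase G6pc 8.06-fold lower and Igfbp1, an insulin-repressed binding protein, 10.2-fold higher (camera adjusted p = 0.085). The lipid droplet gene Hilpda rose 15.1-fold and the lipoprotein receptor Vldlr 10.2-fold, in a list of 20 where 6 rose and 8 fell by either adjustment (camera adjusted p = 0.97). Of 20 bile acid genes 4 rose and 6 fell, or 4 and 7 when adjusted over the list alone, with the sterol hydroxylase Cyp8b1 3.85-fold lower and the efflux pump Abcc4 27-fold higher (camera adjusted p = 0.24). Of 18 clock genes 6 rose and 8 fell by either adjustment, with Dbp, an output factor of the clock, 7.43-fold lower (camera adjusted p = 0.42).

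Of 11 genes of alcohol metabolism 7 fell and none rose, also when adjusted over the list alone, with Adh4 4.36-fold lower (camera adjusted p = 0.017, and adjusted p = 0.66 with an estimated correlation). The ethanol-oxidising Cyp2e1 was 2.05-fold lower (log2 -1.03 ± 0.35, adjusted p = 0.0273). It was at 1110 CPM in EtOH 1 and 4930 to 6790 CPM in the other EtOH libraries, with log2 -0.71 without EtOH 1. Its call ended without PF 1, PF 3 or PF 4, and in a fit of the EtOH and PF libraries alone. Fgf21, a hepatic stress hormone, was 5.7-fold higher (log2 2.51 ± 0.72, adjusted p = 0.0112), and 1.49 without EtOH 4, which ended the call. Among cell type markers, 11 of 16 liver endothelial genes fell and 2 rose, including Lyve1 at 3.6-fold higher, by either adjustment (camera adjusted p = 0.00051, and adjusted p = 0.41 with an estimated correlation). Of 15 monocyte and recruited macrophage markers 6 rose and 2 fell by either adjustment (median log2 0.71, camera adjusted p = 0.12). EtOH 1 stood apart in this list, with a score of 1.63 against -0.01 to 0.3 in the other EtOH libraries. Of 13 stellate cell markers 5 rose and 3 fell by either adjustment, with a median of -0.14 but a mean of 0.23 and camera pointing up (adjusted p = 0.64). Neutrophil markers (1 of 9 rose and 1 fell), Kupffer cell markers (1 of 13 rose and 2 fell) and hepatocyte markers (3 of 14 rose and 1 fell) had camera adjusted p of 0.46, 0.49 and 0.82. The Kupffer cell and hepatocyte lists had medians of -0.06 and -0.03 but means of 0.05 and 0.1, with camera pointing down for the former and up for the latter. The adipocyte gene Cfd was at 11.79 ± 5.89 CPM in PF and 0.0549 ± 0.0403 CPM in EtOH.

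The 4 libraries of each group did not overlap for 36 of the 38 genes named here (not Pdk4 and Fgf21), which the naming rule requires of its largest changes and which is therefore no separate evidence. Chance gives it for 1 of 35 splits. Single libraries moved some folds by more than 1.5 times. Log2 values were 7.76 for Cyp2b10 and 9.48 for Cyp2a4 without PF 4, 7.10 for Cyp2a4 and 3.15 for Srxn1 without EtOH 1, and 2.80 for Pdk4 without EtOH 3. They were -9.07 for Hsd3b5 without PF 2, -10.4 for Hsd3b5 and -7.28 for Mup21 without EtOH 3, and 3.10 for Fgf21 without PF 4. Nqo1, Srxn1, Cyp8b1, Scd1, Pdk4, Hilpda and Ddit3 fall outside the naming rule and were chosen after their values were seen.

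**Figure D2:**
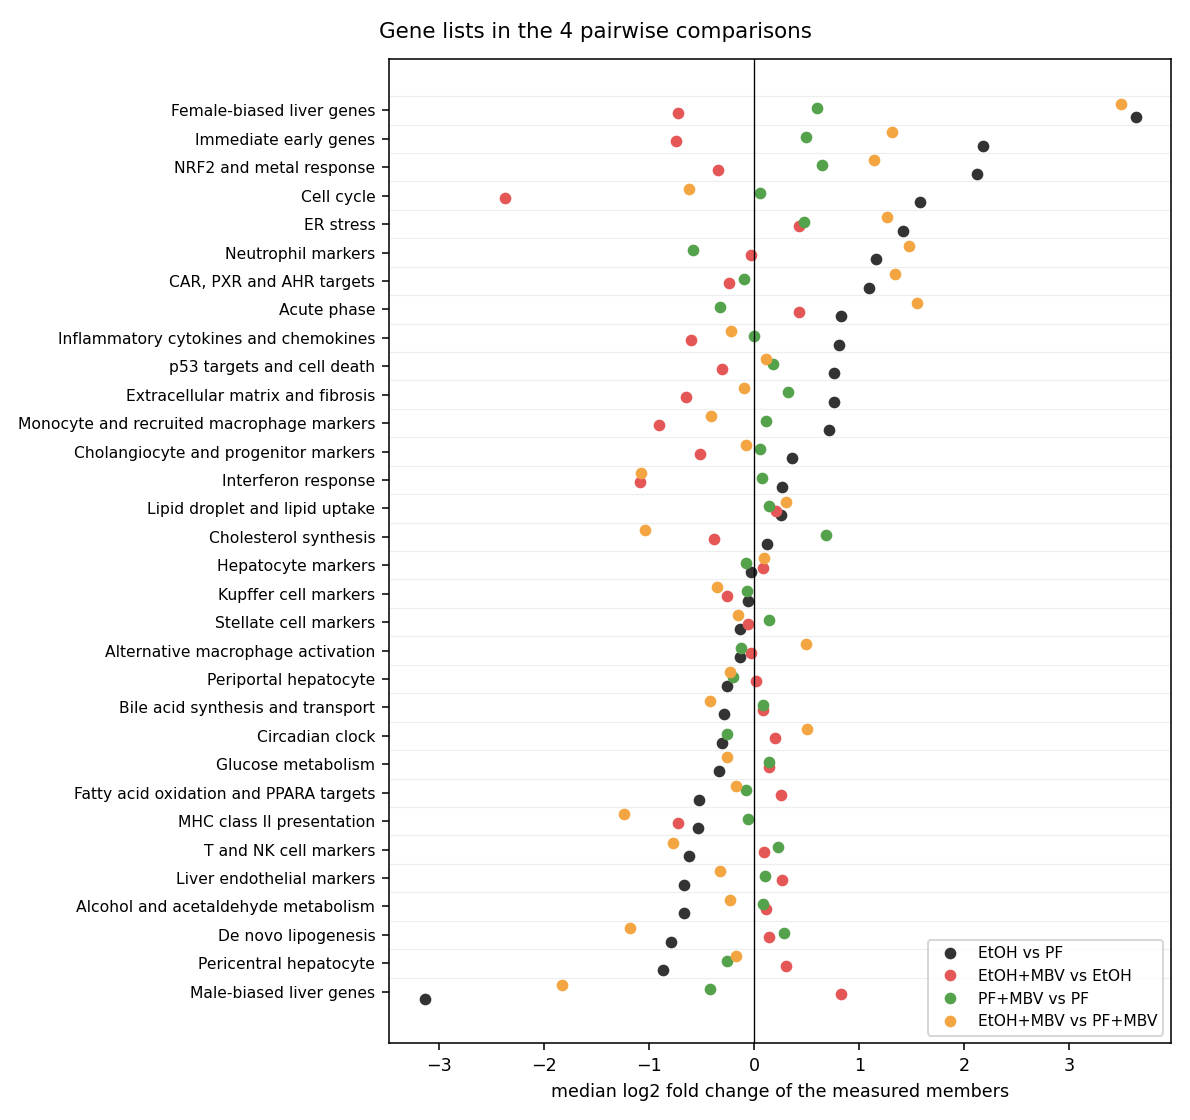
Median log2 fold change of the measured members of each gene list (rows) in the 4 pairwise comparisons (colours). Male-biased liver genes have a median of -3.14 in EtOH against PF, and cell cycle genes -2.37 in EtOH+MBV against EtOH.

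Adding MBV on the ethanol diet changed far fewer genes than the diet did, in both directions. Kit, the stem cell factor receptor, rose 2.68-fold from 2.177 ± 0.591 to 5.795 ± 0.537 CPM (log2 1.42 ± 0.20, edgeR adjusted p = 0.00516), and Clec14a, an endothelial surface protein, rose 2.18-fold (log2 1.12 ± 0.15, adjusted p = 0.00434). The histone gene Hist3h2a rose 5-fold from 0.426 ± 0.149 to 2.108 ± 0.436 CPM. Akap12, a scaffold of protein kinase A, fell 4.43-fold from 53.26 ± 26.9 to 12.04 ± 2.43 CPM (log2 -2.15 ± 0.29, adjusted p = 0.00434), and the heat shock protein Hspa4l fell 2.02-fold (adjusted p = 0.0076). Krt8, a keratin of hepatocytes, fell 2.44-fold from 739.7 ± 290 to 302.8 ± 49.4 CPM (log2 -1.29 ± 0.23, adjusted p = 0.0193). Kit lies on chromosome 5 from 75574987 to 75656722, Clec14a on chromosome 12 from 58264720 to 58269258 and Akap12 on chromosome 10 from 4266329 to 4359471.

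In this comparison 347 genes passed, 160 higher and 187 lower with MBV, and 141 changed at least 2-fold. The count was 64 without EtOH 2, 99 without EtOH 1, 8 without EtOH+MBV 3 and 1169 without EtOH 4, and 7 genes passed whichever single library was left out. In a fit of these 8 libraries alone edgeR called 0 genes, with 1679 at an unadjusted p under 0.05, against 896 by DESeq2 and 143 by limma voom on all 16 libraries. Among the other splits of the 8 libraries the highest count was 742, so chance was not excluded.

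The preset camera test called 17 lists, 11 lower and 6 higher with MBV, and 0 with an estimated correlation (fry called 1). Of 19 inflammatory cytokines and chemokines 3 fell, and 8 when adjusted over the list alone, with Cd14 3.61-fold and the NF-kB inhibitor Nfkbia 1.54-fold lower. Camera gave adjusted p = 1e-06, fry adjusted p = 0.0076, and camera adjusted p = 0.2 with an estimated correlation. Nfkbiz, a relative of Nfkbia, fell 2.01-fold and the chemokine Ccl9 2.11-fold. Of 23 NRF2 and metal response genes 3 fell, or 9 with 2 higher when adjusted over the list alone, with Srxn1 4.22-fold and Txnrd1, the thioredoxin reductase, 1.57-fold lower (camera adjusted p = 0.0001, and adjusted p = 0.5 with an estimated correlation). Of 17 immediate early genes 2 fell, and 9 when adjusted over the list alone (camera adjusted p = 1.8e-07, and adjusted p = 0.47 with an estimated correlation). Of 33 extracellular matrix genes 5 fell, or 14 with 2 higher when adjusted over the list alone, among them the elastase Mmp12 (24.6-fold), the matrix protein Thbs1 (4.76-fold) and the growth factor Tgfb3 (2.74-fold). That list had camera adjusted p = 8.9e-07, and adjusted p = 0.5 with an estimated correlation. The glucose transporter Slc2a1 fell 2.66-fold and the chromatin protein Hmgb2 2.75-fold.

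Several of the lists that were lower with MBV were highest in EtOH 1. Of 35 interferon response genes 5 fell, and 26 when adjusted over the list alone (camera adjusted p = 2.7e-09, and adjusted p = 0.5 with an estimated correlation). Rsad2, an antiviral enzyme, was at 267 CPM in EtOH 1 and at 10.3 to 26.6 CPM in the other EtOH libraries, against 4.743 ± 1.55 CPM in EtOH+MBV. Its log2 fold change was -4.08 ± 0.80, and -1.91 without EtOH 1. The chemokine Cxcl10 was at 21.1 CPM in EtOH 1 and 2.27 to 2.82 CPM in the others, and its log2 fold change of -3.40 ± 0.72 became -1.88 without EtOH 1, with no call. The guanylate-binding Gbp2 fell 3.34-fold. Of 23 cell cycle genes 5 fell, and 19 when adjusted over the list alone (camera adjusted p = 1.1e-06, and adjusted p = 0.53 with an estimated correlation). Top2a, the DNA topoisomerase of dividing cells, was at 23.1 CPM in EtOH 1 and 1.61 to 1.93 CPM in the other EtOH libraries, and its log2 fold change of -3.41 ± 0.80 became -1.37 without EtOH 1. Of 15 monocyte markers 2 fell, and 10 when adjusted over the list alone (camera adjusted p = 0.0001, and adjusted p = 0.5 with an estimated correlation), with a mean score of 1.63 in EtOH 1 and -0.01 to 0.3 in the other EtOH libraries. Cyp2a4 fell 12.1-fold, with 127 CPM in EtOH 1 and 11.4 to 26.7 CPM in the others. Its log2 fold change of -3.60 ± 0.78 became -2.31 without EtOH 1, and -4.50 without EtOH+MBV 2, and its call ended without EtOH 1, EtOH+MBV 3 or EtOH+MBV 4.

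Without EtOH 1 the log2 fold change of Srxn1 also went from -2.08 ± 0.36 to -1.35, that of Mmp12 from -4.62 ± 0.86 to -2.80 and that of Thbs1 from -2.25 ± 0.43 to -1.65. Male-biased genes had camera adjusted p = 0.0002 with a median log2 fold change of 0.83 with MBV, and adjusted p = 0.5 with an estimated correlation. None of the 13 passed and 5 were higher when adjusted over the list alone, with the list score of EtOH+MBV 1 at -1.16 against -3.09 to -2.94 in the other EtOH+MBV libraries. The other lists that camera called higher were fatty acid oxidation (adjusted p = 0.0014), endothelial markers (0.0036), pericentral hepatocyte genes (0.0046), ER stress (0.017) and acute phase (0.017). Their median log2 fold changes were 0.25, 0.26, 0.3, 0.43 and 0.43, and they had adjusted p = 0.67 with an estimated correlation, or adjusted p = 0.5 for the endothelial list. Of these, 1 endothelial and 1 acute phase gene rose and none of the other 3 lists had a call by edgeR. Here too EtOH 1 stood apart, at -1.39 for pericentral genes against -0.13 to -0.01 in the other EtOH libraries, and at -1.21 for fatty acid oxidation against -0.45 to 0.29. Without EtOH 1 camera gave these 2 lists adjusted p = 0.49 and 0.28, ER stress 0.055, acute phase 0.19 and endothelial markers 0.019, so only the last call held. Camera also called MHC class II (1 of 8 fell, and 6 when adjusted over the list alone), p53 target (0 of 20, and 2 fell when adjusted over the list alone) and female-biased genes (1 of 6 fell by either adjustment) lower, with adjusted p = 0.00075, 0.0038 and 0.022, and adjusted p = 0.5 with an estimated correlation for each. The p53 call ended without EtOH 1 (0.059) and the female-biased one without EtOH+MBV 1 (0.14). The nuclear RNA Neat1 rose 2.86-fold, a call that ended without EtOH 1, EtOH 2 or EtOH+MBV 3. Apcs, the serum amyloid P protein, rose 2.06-fold, a call that ended without EtOH 1, EtOH 2, EtOH+MBV 2, EtOH+MBV 3 or EtOH+MBV 4. Of 24 cholesterol synthesis genes 3 fell, also when adjusted over the list alone (camera adjusted p = 0.00023, and adjusted p = 0.67 with an estimated correlation).

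Calls for Kit, Clec14a, Hist3h2a, Akap12 and Hspa4l held whichever library was left out, though not in the fit of these 8 libraries alone, which called no gene. Those of Krt8, Srxn1, Txnrd1, Cd14, Mmp12, Thbs1, Tgfb3, Rsad2, Gbp2, Slc2a1, Ccl9, Nfkbiz and Hmgb2 ended without EtOH+MBV 3. The call of Nfkbia ended without EtOH 2 or EtOH+MBV 3, that of Cxcl10 without EtOH 1, EtOH+MBV 2 or EtOH+MBV 3, and that of Top2a without any of 10 libraries. With 1 surrogate variable Krt8, Txnrd1, Cd14, Thbs1, Tgfb3, Gbp2, Slc2a1, Ccl9, Nfkbia, Neat1, Cyp2a4, Cxcl10, Top2a, Hmgb2 and Apcs were not called. That variable was at 0.893 in EtOH 1 and at -0.18 to 0.088 in the other libraries, so it mostly sets EtOH 1 apart. The libraries of the groups did not overlap for 23 of these 24 genes, which follows largely from how they were chosen and is no separate evidence. Clec14a, Akap12, Hspa4l, Krt8, Slc2a1, Ccl9, Nfkbiz and Hmgb2 were chosen after their values were seen.

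**Figure D3:**
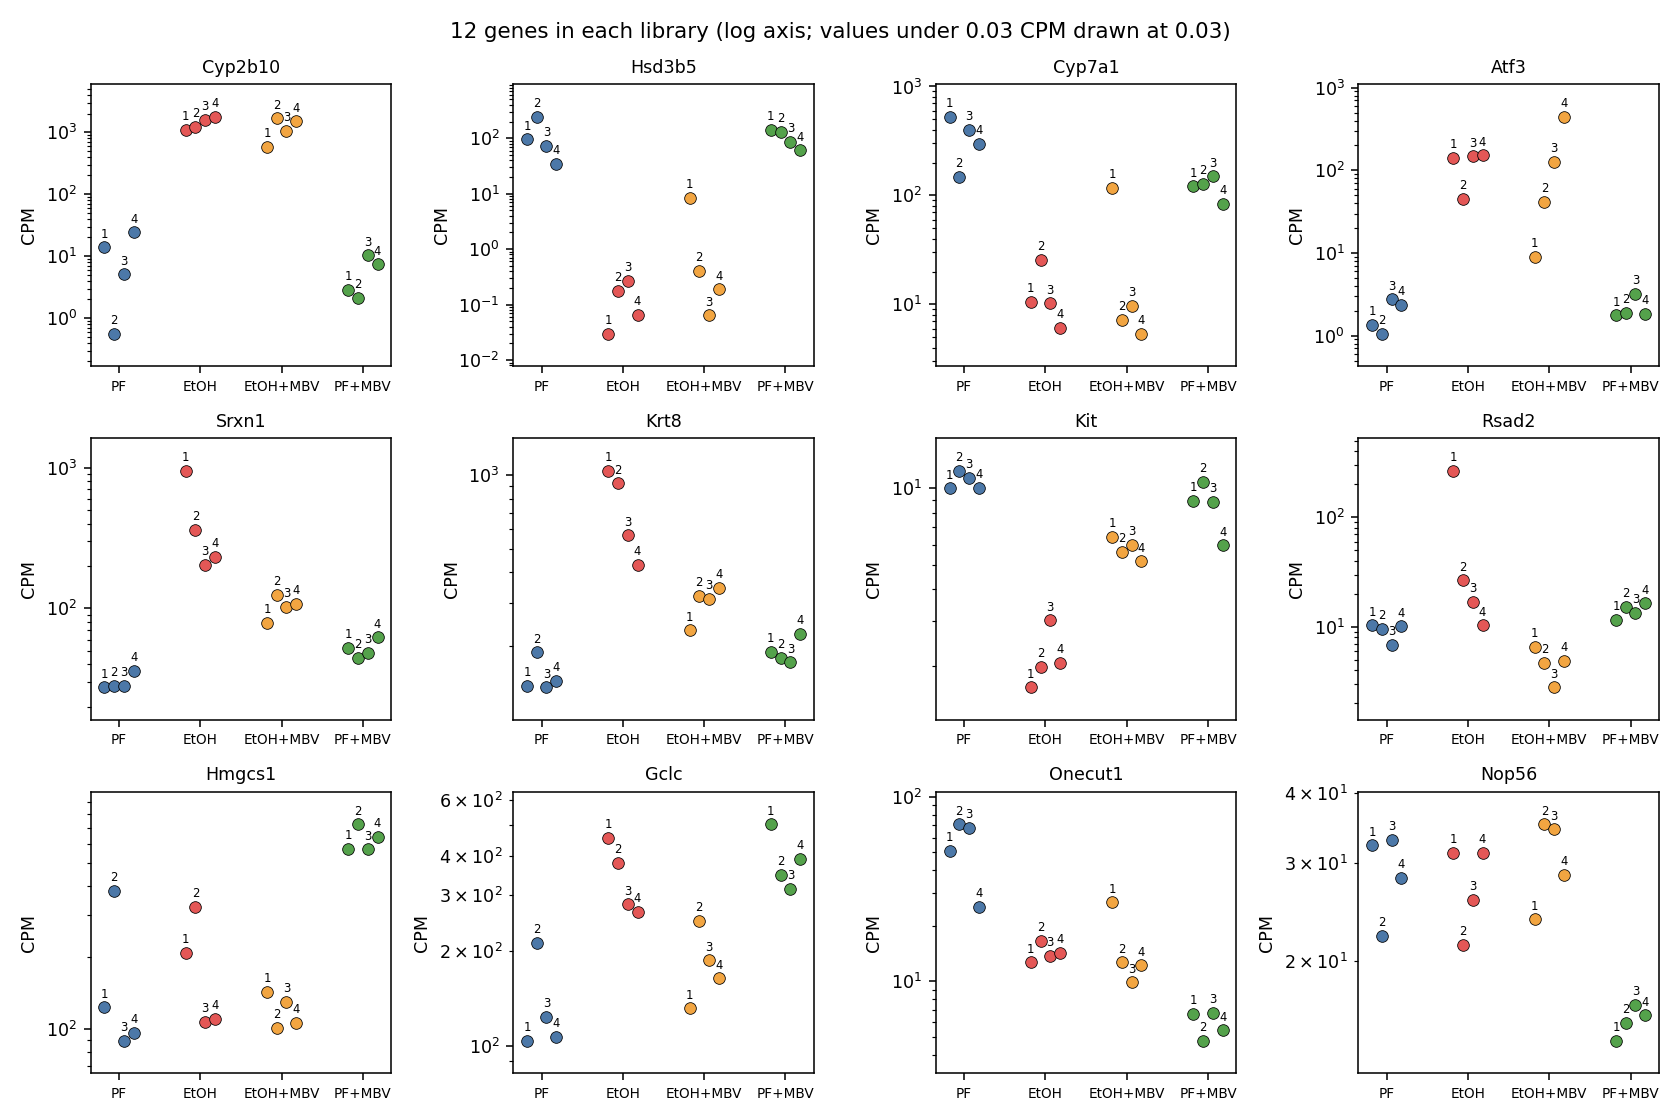
CPM (log axis) of 12 genes in each library, by group, with digits for the replicates and values under 0.03 drawn at 0.03. Rsad2 is at 267 CPM in EtOH 1 and 10.3 to 26.6 CPM in the other EtOH libraries.

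On the control diet single genes of growth control, the cytoskeleton and glutathione synthesis differed between mice with and without MBV. Onecut1, a hepatocyte transcription factor, fell 9.06-fold from 53.62 ± 20.8 to 5.917 ± 0.984 CPM (log2 -3.18 ± 0.33, edgeR adjusted p = 0.000128). Socs2, an inhibitor of growth hormone signalling, fell 5.44-fold from 35.06 ± 7.17 to 6.424 ± 1.65 CPM (log2 -2.44 ± 0.24, adjusted p = 0.000128). Tubb2a, a tubulin, rose 4.47-fold from 26.1 ± 8.16 to 116.7 ± 15.8 CPM (log2 2.16 ± 0.24, adjusted p = 0.000246). Gclc, which limits glutathione synthesis, rose 2.85-fold from 136.8 ± 50.9 to 389.7 ± 82 CPM (log2 1.51 ± 0.25, adjusted p = 0.00906). Onecut1 lies on chromosome 9 from 74861921 to 74889648, Socs2 on chromosome 10 from 95383903 to 95417321, Tubb2a on chromosome 13 from 34074278 to 34078008 and Gclc on chromosome 9 from 77754535 to 77794489.

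In pair-fed livers 230 genes passed, 97 higher and 133 lower with MBV, and 77 changed at least 2-fold. Other methods gave from 192 genes with the stranded column to 2494 with limma voom. DESeq2 gave 649, and edgeR on the PF and PF+MBV libraries alone 1119. The highest count in any other split of these 8 libraries was 0. Leaving out 1 library gave 45 genes without PF 1, 52 without PF 3, 57 without PF+MBV 1, 66 without PF+MBV 2, 71 without PF+MBV 4, 94 without PF+MBV 3, 99 without PF 4, 377 without EtOH+MBV 1, 535 without EtOH 1 and 689 without PF 2, and 40 genes passed every time.

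Of 24 cholesterol synthesis genes 4 rose, and 18 when adjusted over the list alone (camera adjusted p = 3.5e-13, and adjusted p = 0.63 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, was 3.64-fold higher (log2 1.86 ± 0.42, adjusted p = 0.0362). PF 2 held 381 CPM of Hmgcs1 and the other PF libraries 88.9 to 123 CPM, and without PF 2 its log2 fold change was 2.61. Of 20 lipogenesis genes 4 rose, and 6 when adjusted over the list alone, among them Fasn, the fatty acid synthase (2.64-fold), Gpam, the first enzyme of glycerolipid synthesis (1.85-fold), Elovl5 (1.96-fold) and Pnpla3 (5.25-fold). That list had camera adjusted p = 0.00069, and adjusted p = 0.63 with an estimated correlation. The acyl-CoA ligase Acsl3 (1.9-fold), the peroxisomal transporter Abcd2 (2.11-fold), the water channel Aqp8 (3.44-fold), the translation regulator Cpeb2 (2.62-fold) and Nr0b2, a repressor of bile acid synthesis (3.37-fold), rose as well. Of 23 NRF2 and metal response genes 2 rose and 1 fell, or 11 and 2 when adjusted over the list alone (camera adjusted p = 0.0015, and adjusted p = 0.63 with an estimated correlation). They were Gclc, Nqo1 (2.61-fold higher) and the zinc exporter Slc30a1 (1.92-fold lower).

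Of 8 genes of alternative macrophage activation 2 fell, and 3 when adjusted over the list alone (camera adjusted p = 0.025, fry adjusted p = 0.0028, and camera adjusted p = 0.41 with an estimated correlation). Camera also called the extracellular matrix (adjusted p = 0.0057) and ER stress (0.027) lists higher and the acute phase (0.025) and periportal hepatocyte (0.044) lists lower, each with adjusted p = 0.93 with an estimated correlation. Those 4 lists had no member called by edgeR over all genes, while adjusted over the list alone 1 matrix gene was higher and 1 periportal gene lower.

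Of 18 clock genes 1 rose and 2 fell, or 3 and 6 when adjusted over the list alone (camera adjusted p = 0.06). Npas2, which drives the clock, was 11-fold higher at 1.703 ± 0.465 against 0.156 ± 0.149 CPM, and the repressors Per2 and Per3 were 2.44-fold and 2.98-fold lower. Cish, a cytokine-induced inhibitor related to Socs2, fell 4.49-fold, the skin transglutaminase Tgm1 5.23-fold, Nrep 4.34-fold, the amino acid transporter Slc43a1 3.37-fold, the differentiation inhibitor Id2 2.34-fold and the Wnt receptor Fzd4 2.03-fold. Of 39 ribosome assembly genes, a group drawn up after the values were seen, 11 fell, and 26 when adjusted over the list alone, among them Nop56 (1.85-fold), Nolc1 (1.94-fold) and Ppan (2.02-fold). The 35 interferon response and 23 cell cycle genes had medians of 0.07 and 0.05 log2 and no calls by edgeR, also when adjusted over the list alone (camera adjusted p of 0.39 and 0.92).

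The libraries of the groups did not overlap for any of the 28 genes named, which follows largely from how they were chosen and is no separate evidence. Calls of Aqp8 and Npas2 ended without PF 1, and those of Hmgcs1, Nr0b2 and Pnpla3 ended without any of 7 libraries (PF 1, PF 3, PF 4 or each PF+MBV library). Calls of Per2 and Per3 ended without PF 1, PF 3, PF+MBV 1, PF+MBV 2 or PF+MBV 4, that of Fasn without PF 1, PF 3, PF 4 or PF+MBV 2, and that of Cish without PF 3, PF+MBV 1, PF+MBV 2 or PF+MBV 3. The call of Elovl5 ended without PF 1, PF 3, PF 4, PF+MBV 1 or PF+MBV 2, and that of Nqo1 without PF 1, PF 3, PF 4, PF+MBV 1, PF+MBV 3 or PF+MBV 4. Id2, Nop56, Nolc1, Ppan, Fzd4, Acsl3 and Cpeb2 were chosen after their values were seen.

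Ethanol-fed and pair-fed livers were also compared with MBV given on both diets. This comparison does not repeat EtOH against PF, since changes with MBV on either diet enter it as well. Acute phase genes rose, with Lcn2 163-fold higher, at 1373 ± 845 CPM against 8.404 ± 3.38 CPM (log2 7.35 ± 0.83, edgeR adjusted p = 2.01e-05). Cyp2b10 rose 211-fold to 1200 ± 487 CPM (log2 7.72 ± 0.84, adjusted p = 1.47e-05). Fads3, a fatty acid desaturase, fell 14.8-fold from 59.59 ± 14.5 to 3.993 ± 1.31 CPM (log2 -3.89 ± 0.38, adjusted p = 7.55e-06). Hmgcs1 fell 5.21-fold from 626.4 ± 73.2 to 120.2 ± 19.9 CPM (log2 -2.38 ± 0.43, adjusted p = 0.000659). In all, 4633 genes passed, 2478 higher and 2155 lower, and the highest count in any other split was 1. Lcn2 lies on chromosome 2 from 32384637 to 32387739 and Fads3 on chromosome 19 from 10040855 to 10060113.

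Of 26 acute phase genes 20 rose and 1 fell by either adjustment, among them Saa1 (46.5-fold), Saa2 (67.8-fold), Orm3 (31.2-fold, log2 4.96, and 5.76 without PF+MBV 4), the protease inhibitor Serpina3n (8.1-fold) and the interleukin receptor Il1r1 (6.95-fold). Camera gave adjusted p = 3e-07, and adjusted p = 0.55 with an estimated correlation. Saa, Orm and Serpina genes are families that share reads. Of 24 cholesterol synthesis genes 17 fell by either adjustment, with Insig1, a sensor of sterols, 5.23-fold lower (camera adjusted p = 6.1e-08, and adjusted p = 0.55 with an estimated correlation). In EtOH against PF no such fall was seen, as 3 of the 24 rose and 1 fell (camera adjusted p = 0.64). Hmgcs1 was at 568 to 724 CPM in PF+MBV and at 88.9 to 381 CPM in PF. Of 20 lipogenesis genes 15 fell and 1 rose by either adjustment, with Fads2 4.82-fold and Scd1 4.66-fold lower (camera adjusted p = 6.7e-07, and adjusted p = 0.55 with an estimated correlation). Of 35 interferon response genes 21 fell, and 23 when adjusted over the list alone, with Ifi44 6.15-fold lower (camera adjusted p = 1.2e-06, and adjusted p = 0.58 with an estimated correlation). In EtOH against PF 3 of the interferon response list rose and 3 fell (camera adjusted p = 0.77). Gbp10, outside that list, fell 15.7-fold (log2 -3.98, and -4.75 without EtOH+MBV 1). Of 8 MHC class II genes 7 fell by either adjustment (camera adjusted p = 0.00085, and adjusted p = 0.55 with an estimated correlation). Atf3 rose 70.8-fold (log2 6.15 ± 0.92), with 442 CPM in EtOH+MBV 4 and 9.05 to 127 CPM in the other EtOH+MBV libraries, and its log2 fold change was 4.76 without EtOH+MBV 4. Psat1 rose 31.6-fold, and 16 of 22 ER stress genes rose, or 18 when adjusted over the list alone (camera adjusted p = 5.8e-06, and adjusted p = 0.55 with an estimated correlation). The other lists called by camera were CAR, PXR and AHR targets (13 of 17 rose and 1 fell by either adjustment), NRF2 and metal response (14 of 23 rose and 3 fell, or 14 and 4 when adjusted over the list alone), immediate early genes (10 of 17 rose and 2 fell, or 12 and 2) and endothelial markers (1 of 16 rose and 8 fell by either adjustment). Their camera adjusted p were 6.1e-07, 8.8e-05, 0.0018 and 0.006, with adjusted p = 0.49 for the first and adjusted p = 0.55 for the other 3 with an estimated correlation. The female-biased Cux2 rose 53.4-fold, the estrogen sulfotransferase Sult1e1 rose 31.8-fold, and Ppp1r3g, a glycogen-targeting phosphatase subunit, fell 15.6-fold.

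Of 13 male-biased genes 9 fell by either adjustment (camera adjusted p = 3e-05, and adjusted p = 0.55 with an estimated correlation), with Slco1a1 4.28-fold lower. Hsd3b5 was at 8.34 CPM in EtOH+MBV 1 and at 0.0637 to 0.402 CPM in the other EtOH+MBV libraries, and its log2 fold change of -5.45 ± 0.86 became -8.87 without EtOH+MBV 1. Mup21 was at 35.2 CPM in EtOH+MBV 1 and at 1.27 to 3.95 CPM in the others, and its log2 fold change of -3.57 ± 0.79 became -5.77. Cfd was at 23.61 ± 28.8 CPM in PF+MBV and at 0.121 ± 0.112 CPM in EtOH+MBV (log2 -7.50 ± 1.01, and -6.17 without PF+MBV 4, which held 66.3 CPM). The libraries of the groups did not overlap for any of these 23 genes, which follows largely from how they were chosen and is no separate evidence. Each stayed called whichever library was left out, as did 2978 of the 4633 genes. Hmgcs1, Scd1, Ifi44, Il1r1, Serpina3n and Slco1a1 were chosen after their values were seen.

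**Figure D4:**
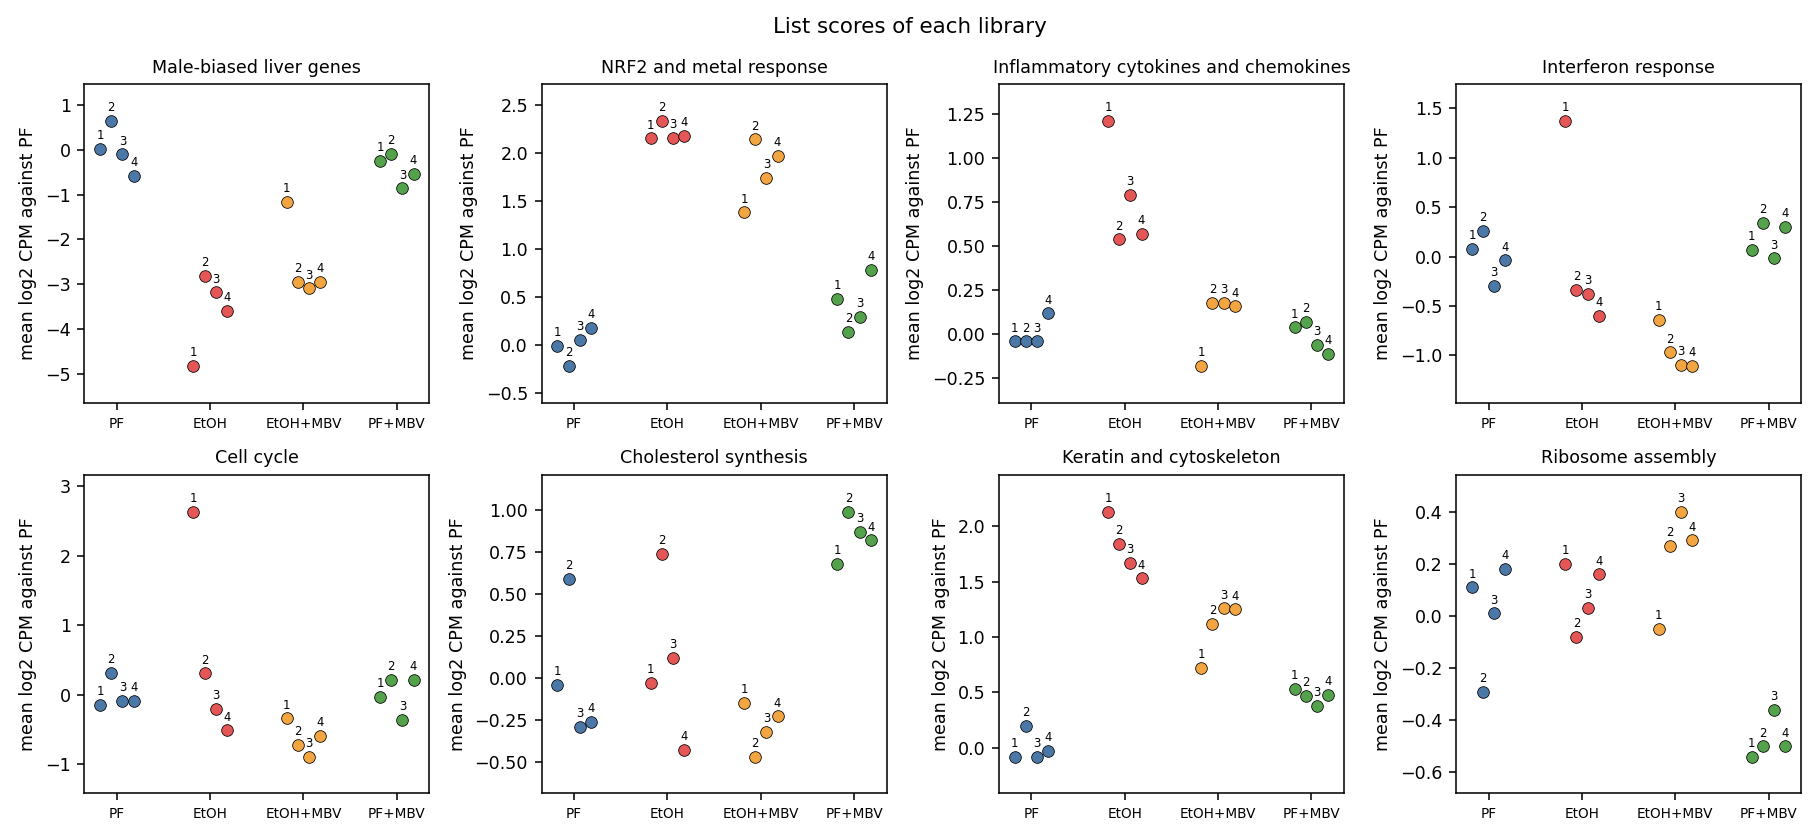
Mean log2 CPM of the members of 8 gene groups in each library, relative to the PF mean, by group with digits for the replicates. EtOH 1 has an interferon response score of 1.37 and EtOH+MBV 1 a male-biased score of -1.16.

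The difference between the MBV effects on the 2 diets was tested as an interaction, which 530 genes passed, 261 with a higher MBV effect on ethanol and 269 with a lower one. Such a difference can come from a change on either diet or on both. The highest count among 99 other regroupings was 241. Insig1, of the sterol genes, was lower in the interaction by a log2 value of -2.29 ± 0.42 (edgeR adjusted p = 0.0137). Of 24 cholesterol synthesis genes 8 were lower in the interaction, and 18 when adjusted over the list alone (camera adjusted p = 3.2e-12, fry adjusted p = 0.037, and camera adjusted p = 0.36 with an estimated correlation). Of 23 NRF2 and metal response genes 9 were lower and 1 higher, or 15 and 4 when adjusted over the list alone, with Gclc at -2.43 ± 0.36, Nqo1 at -2.31 ± 0.41 and Srxn1 at -2.87 ± 0.50 (-2.14 without EtOH 1). That list had camera adjusted p = 1.9e-05, fry adjusted p = 0.026, and camera adjusted p = 0.36 with an estimated correlation. Glutathione reductase, Gsr, stood at -1.21 ± 0.24.

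Of 17 keratin and cytoskeleton genes, a group drawn up after the values were seen, 7 were lower in the interaction, and 14 when adjusted over the list alone. Krt8 stood at -1.62 ± 0.32, its partner Krt18 at -1.53 ± 0.30 and Tubb2a at -2.42 ± 0.34. The log2 fold change of Tubb2a was -0.26 in EtOH+MBV against EtOH, with no call, and 2.16 in PF+MBV against PF. Single genes with a lower MBV effect on ethanol were Pnpla3 (-3.76 ± 0.74, and -2.99 without EtOH 2), Gpam (-1.06 ± 0.21) and Aqp8 (-2.65 ± 0.44). The lipogenesis list, which holds Pnpla3 and Gpam, was not among the lists that camera called in the interaction. Of 33 extracellular matrix genes 6 were lower, or 16 with 1 higher when adjusted over the list alone, with Mmp12 at -5.74 ± 1.21 (-3.92 without EtOH 1 and -6.41 without PF 4) and Tgfb3 at -1.89 ± 0.38 (camera adjusted p = 2.9e-07, and adjusted p = 0.51 with an estimated correlation). Nfkbia stood at -0.99 ± 0.18.

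Genes with a higher MBV effect on ethanol included hepatocyte transcription factors, where 7 of a group of 15 drawn up after the values were seen passed, and 9 when adjusted over the list alone. Onecut1 stood at 3.29 ± 0.44, Hhex at 2.42 ± 0.48 and Prox1 at 1.76 ± 0.37. In EtOH+MBV against EtOH none of the 15 was called, and 6 were higher when adjusted over the list alone. In PF+MBV against PF 2 fell, and 5 when adjusted over the list alone. Onecut1 had a log2 fold change of 0.11 in the former and -3.18 in the latter, so its interaction does not show a rise with MBV on ethanol. The growth factor receptor Egfr stood at 1.79 ± 0.35, Socs2 at 1.87 ± 0.33, Kit at 1.74 ± 0.27, Clec14a at 1.53 ± 0.20 and Hist3h2a at 2.55 ± 0.38. Of 18 clock genes 2 were higher and 1 lower, or 5 and 2 when adjusted over the list alone, with Per2 at 1.79 ± 0.35 and Per3 at 2.23 ± 0.45 (camera adjusted p = 0.089). Of 39 ribosome assembly genes 12 were higher, and 22 when adjusted over the list alone, among them Nop56 (1.04 ± 0.22), Nolc1 (1.11 ± 0.23), Rrp12 (1.5 ± 0.30) and Pdcd11 (1.40 ± 0.26). Of the same 39 genes 1 rose in EtOH+MBV against EtOH, while 11 fell in PF+MBV against PF. The steroid hydroxylase Cyp21a1 stood at 3.88 ± 0.65 and the ferritin receptor Scara5 at 3.39 ± 0.64. All 30 interaction genes named here stayed called whichever library was left out, but only 133 of the 530 genes did. The named genes are thus not typical of the calls. Per3, Nolc1 and Rrp12 were not called with 1 surrogate variable, where 162 genes passed. The count of genes ran from 168 without PF 1 to 1088 without EtOH 4. It was 169 without PF+MBV 4, 187 without PF 3, 190 without PF+MBV 2, 192 without EtOH+MBV 3, 207 without PF+MBV 1, 266 without EtOH 2, 270 without PF+MBV 3, 300 without PF 4, 343 without EtOH+MBV 2 and 853 without PF 2. Gsr, Krt8, Krt18, Tubb2a, Aqp8, Egfr, Prox1, Hhex, Kit, Clec14a, Nop56, Nolc1, Rrp12 and Pdcd11 were chosen after their values were seen.

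Camera called 11 further lists in the interaction. Lower were interferon response (4 of 35 genes, and 14 when adjusted over the list alone), immediate early (5 of 17, and 7), cell cycle (1 of 23, and 7), inflammatory (2 of 19, and 7), p53 target (2 of 20, and 5 with 1 higher), monocyte (1 of 15, and 4) and MHC class II genes (0 of 8 by either adjustment). Their camera adjusted p were 3.4e-07, 2.4e-05, 0.00055, 0.001, 0.0023, 0.0023 and 0.027, with adjusted p = 0.58, 0.36, 0.64, 0.36, 0.36, 0.58 and 0.61 with an estimated correlation. Higher were male-biased (2 of 13, and 7 when adjusted over the list alone), acute phase (2 of 26 by either adjustment), pericentral (1 of 16 by either adjustment) and fatty acid oxidation genes (0 of 23 by either adjustment). Their camera adjusted p were 0.00011, 0.001, 0.0063 and 0.024, with adjusted p = 0.57, 0.61, 0.61 and 0.72 with an estimated correlation. EtOH 1 stood apart in the scores for interferon response (1.37, others -0.6 to -0.34), cell cycle (2.63, others -0.51 to 0.31) and monocyte genes (1.63, others -0.01 to 0.3). Without EtOH 1 camera gave these 3 adjusted p = 7e-07, 0.015 and 0.011, while the calls for MHC class II (0.14), pericentral (0.11) and fatty acid oxidation genes (0.27) ended. That for fatty acid oxidation also ended without EtOH+MBV 1 (0.07).

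**Figure D5:**
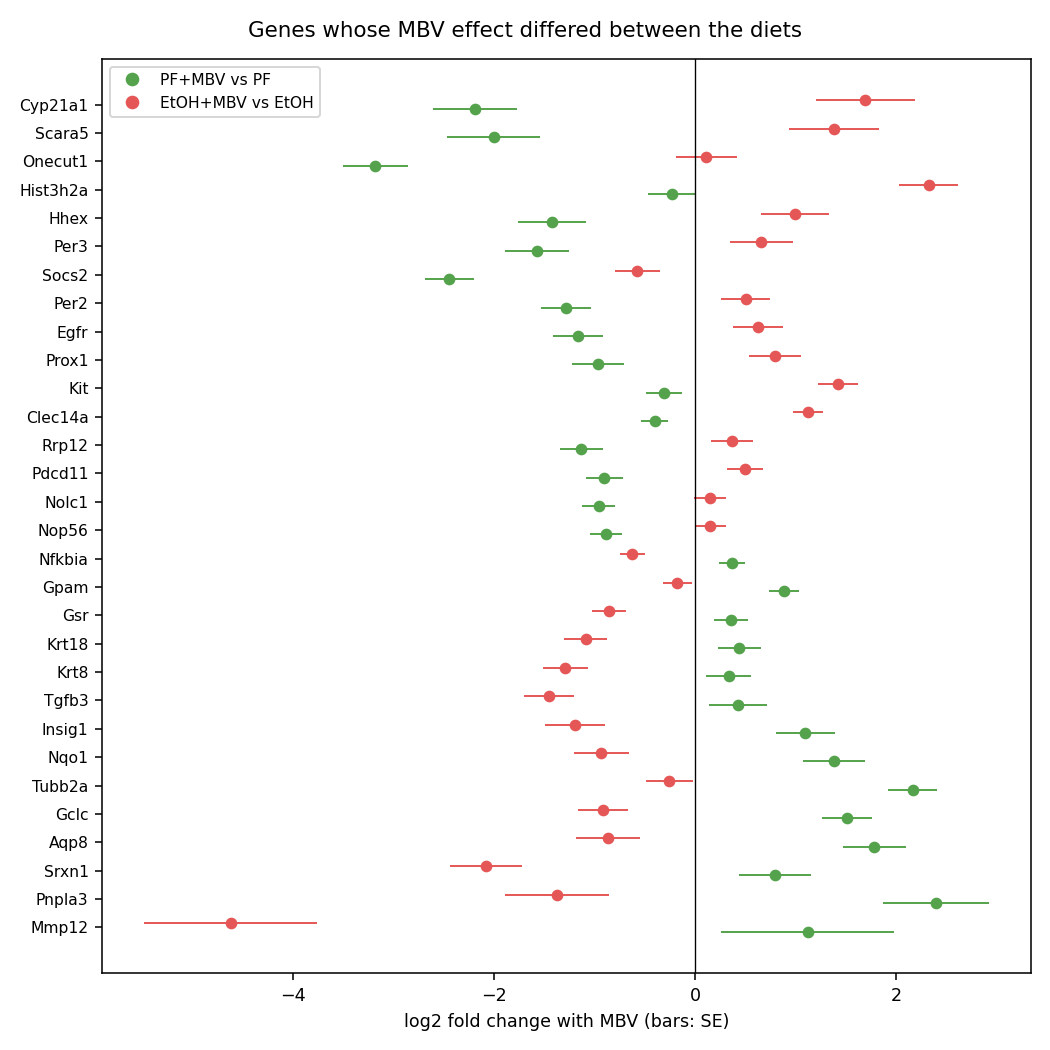
Log2 fold change with MBV (points, bars are SE) of the 30 named interaction genes (rows) on the control diet and on the ethanol diet. Gclc is at 1.51 on the control diet, and Srxn1 at -2.08 on the ethanol diet.

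Genes changed by ethanol mostly had fitted MBV effects of the opposite sign in ethanol-fed livers. Of the 5137 ethanol-called genes 79.7% did, and 66% without EtOH+MBV 1. The share was 60% without EtOH 1 and EtOH+MBV 1, and 61.4% when PF 2 was left out as well. Both contrasts hold the EtOH libraries, and data simulated with no MBV effect gave 58.8% (57.1% to 59.7% over 20 simulations). The simulation drew each gene on its own, while genes of real libraries move together, so its ranges are narrower than chance allows. With 2 EtOH libraries used for each contrast the share was 68.4% (59.9% to 74.7% over 6 splits), against 50.1% simulated. Without EtOH+MBV 1 that share was 56.6% (49.1% to 63.6%). The covariance of the fold changes across genes was -0.245, against -0.0403 simulated. With separate EtOH libraries it was -0.155 against -0.00195 simulated, and -0.0708 when EtOH+MBV 1 was also left out (-0.104 to 0.00422 over the splits). Of 265 genes called in both contrasts 261 had opposite directions. The simulated data gave means of 0.2 and 0.05 genes, but with genes drawn on their own they do not measure chance. Independent lists, which these are not, would give 69.2 opposite genes. Krt8, Srxn1, Cd14 and Mmp12 were among the genes lower with MBV, and Kit among those higher. The ethanol effects with and without MBV correlated across genes at Pearson r = 0.65 (covariance 0.446), or 0.339 with DESeq2 and 0.259 with no low-count filter. In both, 2568 genes were called in the same direction by edgeR, where independent lists would give 924. The MBV effects on the 2 diets correlated across genes at r = -0.195 (covariance -0.0394), or -0.129 without EtOH 1 and -0.105 with 1 surrogate variable. Of 7 genes called in both, 3 had the same direction, where independent lists would give 3.13. Genes are not independent replicates.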

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

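The splits, the distances of libraries, the interaction and the share of opposite changes with and without EtOH+MBV 1 were planned, while the tests on EtOH 1, its depth and cell types, on single PF libraries, on clock genes and on the ethanol axis were chosen only after the results were seen. A library is given here where its distance from the other 3 of its group exceeds Dixon's 95% limit, which chance passes in about 1 in 20 groups. Of the groups examined, 9 of 52 for library measures (17%), 15 of 140 for list scores (11%) and 37 of 428 for named genes (8.6%) passed it. EtOH+MBV 1 accounted for 11 of the genes, EtOH 1 for 8 and PF 2 for 3.

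The genes called differ from chance in 4 of the 5 comparisons. For EtOH against PF, 1 of 35 splits (the real one) gave as many as 5137 genes, with 7 as the highest other. For PF+MBV against PF it was 1 of 35, with 230 genes and 0 as the highest other, and for EtOH+MBV against PF+MBV 1 of 35, with 4633 genes and 1. For the interaction 1 of 100 regroupings gave as many as 530, with 241 as the highest other. For EtOH+MBV against EtOH 2 of 35 splits gave as many as 347, so chance is not excluded. The other one, EtOH+MBV 1 with EtOH 1, EtOH 2 and EtOH 3 against the remaining 4, gave 742. It exchanges only EtOH+MBV 1 and EtOH 4, so it cannot part a treatment effect in the other libraries from another structure of these samples. For the lists called by camera with a preset correlation chance is not excluded in any comparison, with as many lists in 21, 13, 8 and 11 of 35 splits and 45 of 100 regroupings. The real counts were 14, 17, 8, 11 and 14 lists, and the highest others 22, 22, 11, 14 and 22.

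A first pattern is the lower level of interferon, cell cycle, matrix, inflammatory and monocyte genes in EtOH+MBV than in EtOH, with EtOH 1 the highest library in each of these 5 lists. Without EtOH 1 the difference of the inflammatory score was -0.54 against -0.69 with it (exact permutation p = 0.0286, the smallest that 3 against 4 gives), which argues against EtOH 1 alone. The cell cycle score went from -1.19 to -0.5 (exact permutation p = 0.0857) and the monocyte score from -0.76 to -0.38 (exact permutation p = 0.0571). EtOH 1 is thus a candidate source of the cell cycle and monocyte differences. What part EtOH 1 has in the remaining lists stays open. The interferon score was at -0.52 against -0.97 (exact permutation p = 0.0571) and the matrix score at -0.41 against -0.68 (exact permutation p = 0.143). EtOH 1 had a lower hepatocyte score (-0.44, others 0.11 to 0.39) and higher monocyte (by 1.52), Kupffer cell (1.06) and cholangiocyte (0.74) scores than the other EtOH libraries. A lower share of hepatocytes, with the other cell types kept in proportion, would raise every other cell type. The endothelial score instead differed by -0.28 (SD of the others 0.16) and the T and NK cell score, of 5 genes, by -0.99 (SD 0.41). These values argue against that simple change as the whole cause. They cannot speak against a gain of some cell types, which would dilute hepatocytes and the rest. The depth of EtOH 1, 16.3 M within 15.9 to 17.3 M, argues against depth, and an effect of MBV stays open.

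A second pattern is the higher level of cholesterol synthesis genes in PF+MBV than in PF. The smallest difference of the list score without 1 PF library was 0.74, against 0.84 with all, and the libraries did not overlap, which argues against 1 PF library as the cause. Of 18 clock genes 9 passed when adjusted over the list alone, against a 95th percentile of 4 and a maximum of 10 among 10000 random sets of genes. Sterol genes follow the time of day and the last meal in liver, so a difference in the time of sampling or feeding between the 2 groups may account for some of the change, and the labels give neither. An effect of MBV on sterol genes stays open, since it and the time of sampling cannot be told apart here. The same limit holds for the other genes called between these groups and for the interaction, which uses the same libraries. It also extends to EtOH+MBV against PF+MBV, which holds the PF+MBV libraries.

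The last pattern weighed is that ethanol-changed genes moved the opposite way with MBV in ethanol-fed livers. With separate EtOH libraries for each contrast the share was 68.4% against 50.1% simulated, which argues against shared libraries as the whole cause. The simulation drew each gene on its own, so its range lacks the spread of genes that move together. Chance is therefore not excluded as a source of the share. Without EtOH+MBV 1 it was 56.6% (49.1% to 63.6% over the splits), so a role of this library stays open. An axis was drawn from the mean of all pair-fed libraries to the mean of all ethanol-fed ones, with and without MBV. On it EtOH+MBV 1 lay at 0.537 and the other 3 EtOH+MBV libraries at 1.018 to 1.117. The EtOH+MBV libraries, EtOH+MBV 1 among them, thus help to set the axis on which they are placed. The difference between the EtOH+MBV and EtOH means was -0.149 (SD of the 8 libraries 0.195, exact permutation p = 0.371). It was -0.019 with EtOH+MBV 1 left out of the means but not of the axis (exact permutation p = 0.714). A shift of the group was therefore not shown. EtOH+MBV 1 lies outside the ranges of PF (-0.093 to 0.082), PF+MBV (-0.035 to 0.028) and EtOH (0.981 to 1.136), which a label exchanged among these groups would not give. A partial return towards pair-fed levels and a lower intake of ethanol in that mouse could each do so, and no test here parts them.

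Genes in which EtOH+MBV 1 stood apart were Hsd3b5 (8.34 CPM, others at most 0.402), Mup21 (35.2), Cyp4a12b (47.3), Cyp7a1 (117, others at most 9.62), Cyp8b1 (513), Fads2 (445), Adh4 (51.9), Dbp (17.2), G6pc (498) and Onecut1 (26.8), all higher, and Cdkn1a (125), lower. Its scores were -1.16 for male-biased and 1.39 for female-biased genes, -0.13 for alcohol metabolism and -0.18 for inflammatory genes. Its first principal component was -0.3 and its 10 highest genes held 17.51% of counts, against 19.22% to 19.38%.

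EtOH 1 was higher in Cyp2a4 (127 CPM), Mmp12 (31.4), Rsad2 (267), Cxcl10 (21.1), Top2a (23.1), Ifi44 (16) and Gbp10 (3.48), and lower in Lyve1 (78.3). Its list scores were 1.37 for interferon response, 1.22 for CAR, PXR and AHR targets, -1.05 for glucose metabolism, -1.39 for pericentral hepatocytes and -2.09 for red blood cell genes. PF 2 was higher in Hmgcs1 (381 CPM), Insig1 (278) and Krt8 (189), had list scores of 0.32 for cell cycle and -0.14 for clock genes, and lay at -6.6 on principal component 2 and at 2.2 on component 3.

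Other libraries stood apart in single values. EtOH 3 held 1410 CPM of Saa1 and 891 of Saa2, against at most 88.9 and 41.7 in the other EtOH libraries. EtOH 2 held 45.3 CPM of Atf3 and an NRF2 and metal response score of 2.33. EtOH+MBV 2 held 14.5 CPM of Cbr3 and 60.7 of Abcc4, EtOH+MBV 4 43.6 of Socs2, and EtOH+MBV 3 lay at -7.8 on principal component 3. PF 3 held 3.64 CPM of Hist3h2a. PF 4 held 35.8 CPM of Srxn1 and 1.3 of Mmp12, an inflammatory score of 0.12 and 50.58% of stranded reads in 1 column. PF+MBV 1 held 1.29 CPM of Vldlr and 11.2 of Slc2a1. PF+MBV 2 held 8.87 CPM of Ddit3 and 16.04% unmapped reads. PF+MBV 3 held 3.18 CPM of Atf3, scores of -0.04 for B and plasma cell and -0.08 for red blood cell genes, a scaling factor of 1.016 and -4.2 on principal component 2. PF+MBV 4 held 64.1 CPM of Gstm3 and 66.3 of Cfd.

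By the interaction test, the change seen with MBV differed between the diets for 530 genes. The test holds the PF and PF+MBV libraries, so a difference in their time of sampling or feeding would enter it too. Among the named genes the log2 difference was negative for Insig1 (-2.29), Gclc (-2.43), Nqo1 (-2.31), Srxn1 (-2.87), Gsr (-1.21), Mmp12 (-5.74), Krt8 (-1.62), Krt18 (-1.53), Tubb2a (-2.42), Pnpla3 (-3.76), Gpam (-1.06), Aqp8 (-2.65), Tgfb3 (-1.89) and Nfkbia (-0.99). It was positive for Onecut1 (3.29), Egfr (1.79), Prox1 (1.76), Hhex (2.42), Socs2 (1.87), Kit (1.74), Clec14a (1.53), Hist3h2a (2.55), Per2 (1.79), Per3 (2.23), Nop56 (1.04), Nolc1 (1.11), Rrp12 (1.5), Pdcd11 (1.4), Cyp21a1 (3.88) and Scara5 (3.39). Outside the gene counts, reads that mapped to several places made up 6.753% ± 0.921 of the EtOH libraries and 5.078% ± 0.345 of the PF libraries (exact permutation p = 0.0286, adjusted p = 0.0857).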

How the results depend on the processing

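Leaving out 2 or 3 libraries together, and camera without single libraries, were chosen after seeing the data, and the other alternatives were planned. Of the values of named genes under the alternatives, 3676 kept direction and side of the threshold, 155 kept direction only and 0 reversed. These genes were all called in the main fit, and many were chosen after their values were seen, so their choice in part fixes this stability. Of all called genes, 7 of 347 in EtOH+MBV against EtOH and 40 of 230 in PF+MBV against PF stayed called whichever library was left out. Counts of genes stayed within 1.5 times in 79 cases and moved in 55. The cause was not tested for any move.

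The surrogate variable was at 0.893 in EtOH 1 and at -0.18 to 0.088 in the other libraries, so a fit with it mostly discounts EtOH 1. For EtOH+MBV against EtOH, 347 genes became 896 with DESeq2 (341 shared), 143 with limma voom and quality weights (128 shared), 214 with the stranded column and 23 with 1 surrogate variable (21 shared). With only the 2 groups compared edgeR called 0 (1679 at an unadjusted p under 0.05), and without EtOH 1 and EtOH+MBV 1 there were 180 (113 shared). Leaving out 1 library gave 8 to 1169. For PF+MBV against PF, 230 became 649 with DESeq2 (227 shared), 2494 with voom, 1119 with only the 2 groups and 490 with 1 surrogate variable (230 shared each for voom and the surrogate variable). It was 1901 without PF 2, EtOH 1 and EtOH+MBV 1, 1022 without the last 2, and 45 to 689 without 1 library. EtOH+MBV against PF+MBV had 7080 with voom, against 4633. The interaction went from 530 to 1097 with DESeq2, 1410 with voom, 353 with the stranded column, 162 with 1 surrogate variable, 1735 and 887 without those 3 and 2 libraries, and 168 to 1088 without 1.

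The replicate numbers do not pair the libraries. The median correlation of 24 pairs with the same number was 0.014, and 0 libraries correlated best with their own number. With the number as a replicate block EtOH+MBV against EtOH had 205 genes.

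The share of ethanol-called genes moved the opposite way was 61.4% without those 3 libraries and 60% without 2. Data simulated for all libraries with no MBV effect gave 58.8%. The correlation of the ethanol effects was 0.339 with DESeq2 and 0.259 with no low-count filter. That of the MBV effects was -0.122 with DESeq2, -0.12 with no filter, -0.105 with 1 surrogate variable, and -0.124 and -0.109 without 3 and 2 libraries. Camera with an estimated correlation called 0 lists in all 5 comparisons, where it called 14, 17, 8, 11 and 14 with the preset one. Fry called 14, 1, 1, 14 and 5, and camera without those 3 libraries called 8 in the interaction.

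With these depths, and with genes drawn on their own at the same spread in all groups, the simulated 2-fold changes were recovered in 66% to 72% of genes in pairwise comparisons. In the interaction 47% were recovered.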

Other observations

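In this polyadenylated RNA, 5 of 6 measured histone genes of the Hist clusters, among them Hist3h2a, were lower with ethanol. RNA without a poly-A tail was not measured, and the group was drawn up after the values were seen. Of 11 genes of serine and one-carbon metabolism, drawn up likewise, 10 rose and 1 fell with ethanol, Psat1 the named example, and 7 rose and 1 fell with ethanol when MBV was given on both diets. Of 39 ribosome assembly genes 30 were higher in EtOH+MBV than in PF+MBV and 1 lower, while 3 were higher and 4 lower in EtOH than in PF.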
